A study of Mus musculus with 24 samples.

How the data were processed

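Bulk RNA sequencing of sorted mouse CD4 T cells was analysed in 24 libraries, 6 for each of 4 cell states. Each library is deposited as a table of whole-number read counts per gene, not normalised. Per the labels' protocols, cells were frozen in a phenol reagent, RNA was extracted on columns and libraries were made with a kit that keeps the strand of the RNA. Per the submitters' processing notes, STAR, HTSeq and DESeq2 were used with the mouse genome build mm10. Their roles, versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so a gene and an overlapping gene on the other strand may have been counted together. Among the genes named by the rule given below this concerns Fosl1, Il2, Xcl1, Tnfrsf9, Ctsb, Ccr9, Cd27, Ccna2, Nhp2, Acss2, Zbtb7b, Cd160, Shmt1, H2-DMa, Tpi1, Lss and Cd247, whose values are uncertain to that extent. Genes named outside that rule, among them Xist, and genes without 1 GENCODE M21 entry were not checked for overlaps. Xkrx overlaps a gene on its own strand and is uncertain for that reason. Reads shared with near-identical copies are uncertain too, for example for Tpi1, Npm1 and Cycs, which have processed pseudogenes, and for members of the Ifit, Oas and H2 families. Reads of the reporter transgene were not analysed here.

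The groups were taken from the labels. The run was taken from the flow cell part of the file names, which puts numbers 1 to 3 of each group in one run and 4 to 6 in the other. The labels do not say that the 6 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries. No pair of libraries of a group was alike within sampling noise, the lowest chi-square per degree of freedom being 9.21. Each table holds 23420 gene symbols and 5 lines for reads not given to a gene, which stayed out of library sizes and tests. Beside the counts given to genes, reads that met no counted feature made up 23.1% in naive and 22.8% in activated naive libraries on average. They made up 17.2% in TH1 effector and 15.6% in reactivated TH1 libraries. As the annotation and strand setting are not given, they may include reads within genes. Ambiguous reads made up 0.901%, 0.749%, 1.11% and 0.967%, and reads aligned to more than 1 place 5.92%, 6.63%, 7.53% and 6.91%. At least 1 count was found for 13040, 13260, 14353 and 14357 genes on average.

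The counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1 (statmod 1.5.0). Genes were filtered with filterByExpr on the groups, which left 12584, libraries were scaled with TMM factors, and 1 quasi-likelihood model with robust dispersions was fitted to all 24 libraries with group and run as terms. Contrasts were tested with glmQLFTest, adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted p. These 5 contrasts were activated naive against naive, TH1 effector against naive, reactivated TH1 against TH1 effector, reactivated TH1 against activated naive, and the response of TH1 cells minus that of naive cells. All adjusted p-values of genes are from edgeR unless another tool is named. The SE beside a log2 fold change is that of the difference between group means of log2 CPM, from the spread within group and run. Where a group had no counts, the fold is a lower bound against 3 counts over the 6 libraries of that group, and where it had 1 to 3 counts, the ratio is given with its exact 95% interval. Such floors and intervals cover counting error only.

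Lists of genes were written down from textbook knowledge before the data were examined, as were the groups, the model and the other settings to try. They number 28: immediate-early and T cell receptor response, feedback regulators of receptor signalling, TH1 programme, other helper lineages, naive and quiescence genes, cytokines and chemokines, costimulatory and inhibitory receptors, glycolysis, oxidative phosphorylation, fatty acid oxidation, cell cycle, ribosome production and MYC targets, cholesterol and lipid synthesis, amino acid supply and ATF4, NF-kB targets, interferon response, hypoxia, heat shock and protein folding, apoptosis and survival, migration and adhesion, MHC class II, T cell identity, sex-linked genes, and markers of macrophages, B cells, dendritic cells, CD8, NK and innate cells, and neutrophils and red cells. The 27 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and the result with an estimated correlation is given beside each call. The list of neutrophil and red cell markers had 2 tested members, Cxcr2 and Mmp9, and no list test. Among T cell genes named in more than 1 list, each counts under all of its lists.

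Genes were named by a rule set beforehand. For each contrast it takes the 5 largest positive and 5 largest negative log2 fold changes among genes past the threshold with at least 10 CPM in the higher group and, between groups, no overlap of libraries, leaving out predicted genes, receptor segments and small RNAs. It adds Nr4a1, Ifng, Tbx21, Il2, Cd44 and Tcf7 in every contrast, and 1 more gene that is not reported here. From each list called it takes up to 2 members per direction with at least 10 CPM, and from the marker and T cell identity lists the 2 most abundant members. It took 195 genes, most of which are named in the text, with a few examples per list. Genes named outside it are said to have been chosen after their values were seen. Coordinates are from GENCODE M21 (mm10), in which 190 of the 195 genes had 1 entry.

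The replicate numbers pair the libraries. All 36 pairs of libraries with the same number in different groups deviated together from their group means, with correlations from 0.106 to 0.43 (median 0.265, against −0.0835 for different numbers), and 23 of 24 libraries were closest to their own number. Y-linked genes or Xist were expressed in the same pattern in all 4 groups for all 6 numbers, 3 of each kind. This was settled before fits with the number as a block were compared.

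On simulated counts of 12081 genes for activated naive against naive cells, the model called 50 of 50 genes changed 4-fold, 48 of 50 at 2-fold, 42 of 50 at 1.5-fold and 20 of 50 at 1.25-fold, with 2 of 11838 unchanged genes called. For the difference between the responses (12068 genes) it called 50, 47, 29 and 8 of 50, with 7 of 11825 unchanged genes. In each simulated contrast a list shifted 1.5-fold was found and none of 26 other lists was called. The simulated genes were drawn independently from naive means, with few genes changed and no pairing of libraries. The simulation therefore does not check the list test for genes that move together, nor gene calls where most genes change.

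The other settings chosen beforehand were DESeq2 size factors (as computed in edgeR) or library size alone in place of TMM, no filter on low counts or at least 10 CPM in a group, the DESeq2 1.42.0 Wald test, a test against a minimum change of 1.5-fold (glmTreat), no run term, the number as a block, a fit of the groups compared only, each run alone, each number left out in turn, camera with an estimated correlation, and fry. Leaving out numbers 5 and 6 together was chosen after seeing the data. Groups were also exchanged in 100 drawn splits of the libraries per comparison, and in 70 for the difference between the responses. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.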

Results

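RNA was sequenced from mouse CD4 T cells cultured and sorted in vitro. The animals carried the OT-II T cell receptor transgenes, which give nearly all CD4 T cells one receptor for an ovalbumin peptide, and a reporter in which the Nr4a1 (Nur77) promoter drives green fluorescent protein, on a C57BL/6 background. There were 4 groups of 6 libraries each. Naive cells came from spleens, and activated naive cells had been stimulated for 6 hours (the labels used here do not name the stimulus). TH1 effector cells had been differentiated for 5 days towards the interferon-gamma-producing helper type, and reactivated TH1 cells had then met macrophages loaded with antigen for 6 hours. The counts assigned to genes ranged from 18457653 to 34262645 per library, with means of 22938456 in naive, 27302327 in activated naive, 27106546 in TH1 effector and 29181829 in reactivated TH1 libraries (SD 4071296, 4659455, 6087731 and 4548703, n = 6 each). The libraries came from 2 sequencing runs, each with 3 libraries of every group, and averaged 30790064 counts in the first run and 22474515 in the second. The first principal component held 55.2% of the variance and separated the naive and activated naive from the TH1 libraries, and the second, with 30.6%, separated resting from stimulated libraries. Of 23420 genes in the files, 12584 had enough counts to be tested.

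The genes that define these cells differed between the states, but not each of them between every pair. In TH1 effector against naive libraries Nr4a1 did not pass the test. Il2 did not pass there with edgeR (adjusted p = 0.143) but did with the DESeq2 Wald test (0.00297). Ifng, which encodes interferon gamma (chromosome 10, 118441046 to 118445892 in mm10), averaged 0.112 ± 0.101 CPM in naive, 0.482 ± 0.236 in activated naive, 198 ± 62.1 in TH1 effector and 12950 ± 4025 CPM in reactivated TH1 libraries (mean ± SD, n = 6, CPM being normalised counts scaled to a common library total). Tbx21, which encodes the TH1 transcription factor T-bet (chromosome 11, 97098071 to 97115331), averaged 0.116, 38.3, 98.8 and 193 CPM in the same order. Il2, the gene of interleukin 2 (chromosome 3, 37120523 to 37125959), had no counts in naive libraries, where the depth allows up to 0.0205 CPM, and averaged 16.7 ± 6.73 CPM in activated naive, 0.0571 ± 0.0386 in TH1 effector and 409 ± 160 CPM in reactivated TH1 libraries. Nr4a1, whose promoter drives the reporter (chromosome 15, 101254269 to 101274795), averaged 434 ± 199 CPM in naive, 9046 ± 2500 in activated naive, 298 ± 160 in TH1 effector and 790.0 ± 639 CPM in reactivated TH1 libraries.

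**Figure D1:**
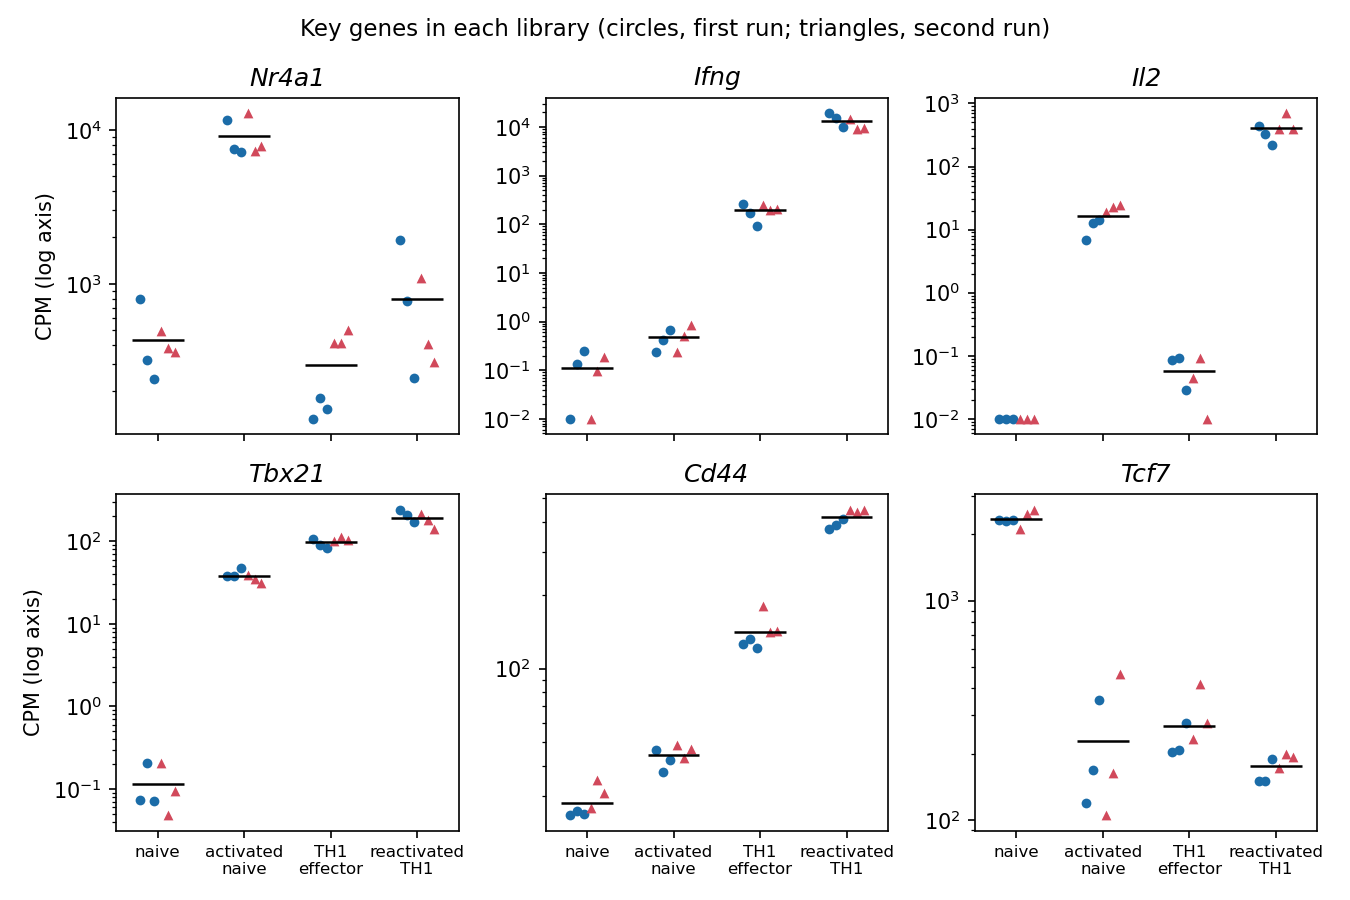
Normalised counts (CPM, log axis) of Nr4a1, Ifng, Il2, Tbx21, Cd44 and Tcf7 in the 6 libraries of each group. Each point is 1 library and each horizontal line the mean of 6 libraries, and values under 0.01 CPM are drawn at 0.01. Nr4a1 was highest in activated naive libraries (mean 9046 CPM) and Ifng in reactivated TH1 libraries (mean 12950 CPM).

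The first comparison asked what naive CD4 T cells change within 6 hours of stimulation. In stimulated naive cells all genes of the list of ribosome production and MYC targets rose, as did most immediate-early and cytokine genes, and most naive and quiescence genes fell. With an estimated correlation the adjusted p of these lists was 0.0103, 0.0595, 0.215 and 0.103, so that the call of the first was kept and the others were lost. Nr4a1 rose 20.8-fold (log2 fold change 4.38, SE 0.32, adjusted p = 1.76e-07), and Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose from 1.45 to 552 CPM. Il2 was at least 774-fold higher than the level that 3 counts over the 6 naive libraries would give, and the transcription factor genes Atf3 and Fosl1, also without counts in naive cells, were at least 4210-fold and 2180-fold higher. Il7r, the interleukin 7 receptor gene, fell from 420 to 1.67 CPM. In all, 10303 of 12584 genes passed the test, 5201 higher and 5102 lower, of which 2671 and 2924 changed at least 2-fold. The runs fitted alone gave 9788 and 9270 genes.

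Several gene lists fixed beforehand moved as groups in stimulated naive cells. All 43 genes of ribosome production and MYC targets rose (list adjusted p = 1.75e-45), among them Odc1 (24.7-fold) and Srm (13.8-fold), both enzymes of polyamine synthesis, and this call held with an estimated correlation (adjusted p = 0.0103). Of 36 genes of amino acid supply and the ATF4 stress response, 31 rose and 1, Ddit4, fell (adjusted p = 4.43e-18, and 0.0656 with an estimated correlation). The cystine transporter gene Slc7a11 went from 0.0493 to 19.1 CPM and Asns, which makes asparagine, from 0.117 to 10.6 CPM. Of 25 immediate-early and T cell receptor response genes, 20 rose and 5 fell (adjusted p = 9.73e-07, and 0.0595 with an estimated correlation). Among those that fell were the AP-1 genes Fosb (198 to 3.67 CPM) and Jun (549 to 18.4 CPM), which resting libraries held at a high level. Of 32 naive and quiescence genes 25 fell and 5 rose (adjusted p = 1.24e-06, and 0.103 with an estimated correlation). Nsg2 went from 376 to 2.82 CPM, while the transcription regulators Bach2 (3.41-fold) and Id3 (2.88-fold) rose. Among 39 cytokine genes 23 rose and 3 fell (adjusted p = 0.00962, and 0.215 with an estimated correlation). The chemokine gene Xcl1 went from 0.0442 to 41.3 CPM, whereas Ltb (448 to 149 CPM) and Tnfsf10 (6.14-fold) fell. Of 33 costimulatory and inhibitory receptor genes 22 rose, such as Slamf7 (487-fold), and 5 fell, such as Cd226 (59.4 to 2.05 CPM) (adjusted p = 0.00152, and 0.0656 with an estimated correlation).

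Of 35 heat shock and protein folding genes 28 rose, led by Hspa4l (16.0-fold), and 6 fell, among them the co-chaperone gene Dnajb1 (2.21-fold) (adjusted p = 1.53e-08, and 0.163 with an estimated correlation). Among 31 NF-kB targets 21 rose and 5 fell, including Bcl3 (8.78-fold lower) (adjusted p = 0.00152, and 0.215 with an estimated correlation). For oxidative phosphorylation, 40 of 49 genes rose and 6 fell, with Cycs, cytochrome c, 4.43-fold higher and Sdha 1.30-fold lower (adjusted p = 0.00159, and 0.683 with an estimated correlation). In the interferon-response list 45 of 56 genes fell and 3 rose (adjusted p = 0.0131, and 0.843 with an estimated correlation). Ifit3 went from 86.9 to 9.17 CPM and Ddx60 from 121 to 12.6 CPM, and Irf8 rose from 9.13 to 219 CPM. The libraries of this group did not hold the list at one level, with a mean log2 CPM of 6.30 and 6.13 in numbers 5 and 6 against 4.46, 4.46, 4.88 and 4.88 in numbers 1 to 4. Of 22 fatty acid oxidation genes 14 fell, such as Cpt1a (6.52-fold) and Hadh (8.40-fold), and 6 rose, such as Acot7 (18.9-fold) (adjusted p = 0.0356, and 0.215 with an estimated correlation). Their call was lost in each run alone (adjusted p = 0.0612 and 0.0535), without number 5 (0.0596) and when genes needed 10 CPM in a group (0.0566). Among 31 feedback regulators of receptor signalling 17 rose, such as Rgs16 (0.219 to 426 CPM) and Spry1 (1.06 to 550 CPM), and 10 fell, such as Socs3 (69.5-fold) and the adaptor gene Sla2 (17.9-fold). This list had an adjusted p of 0.0470, or 0.416 with an estimated correlation, and the call was lost with replicate number as a block (0.153), in the first run (0.0660), without number 5 (0.0674) or 6 (0.0648), without both (0.104, chosen after the data were seen), with no filter on low counts (0.146) and when genes needed 10 CPM in a group (0.0819). With p-values adjusted over the list alone, the counts of passing members were the same in these 12 lists. The other 15 lists had adjusted p-values from 0.0694 to 0.949, the lowest for glycolysis, which passed with scaling by library size only (0.0481), in the first run alone (0.0496) and in a fit of the naive and activated naive libraries only (0.0114), in which other helper lineages (0.161) passed too (0.00986). They were the TH1 programme, other helper lineages, glycolysis, cell cycle, cholesterol and lipid synthesis, hypoxia, apoptosis and survival, migration and adhesion, T cell identity, the sex-linked genes, MHC class II, and the markers of macrophages, B cells, dendritic cells and CD8, NK and innate cells. Ifng passed the test (3.92-fold, log2 1.97, SE 1.26, adjusted p = 0.0178) at a level under 1 CPM, and the call was lost without number 4 (adjusted p = 0.0518) or 6 (0.0530), without both 5 and 6 (0.161) and in the first run alone (0.225). Over 16 alternatives its adjusted p ran from 6.91e-05 to 0.225.

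**Figure D2:**
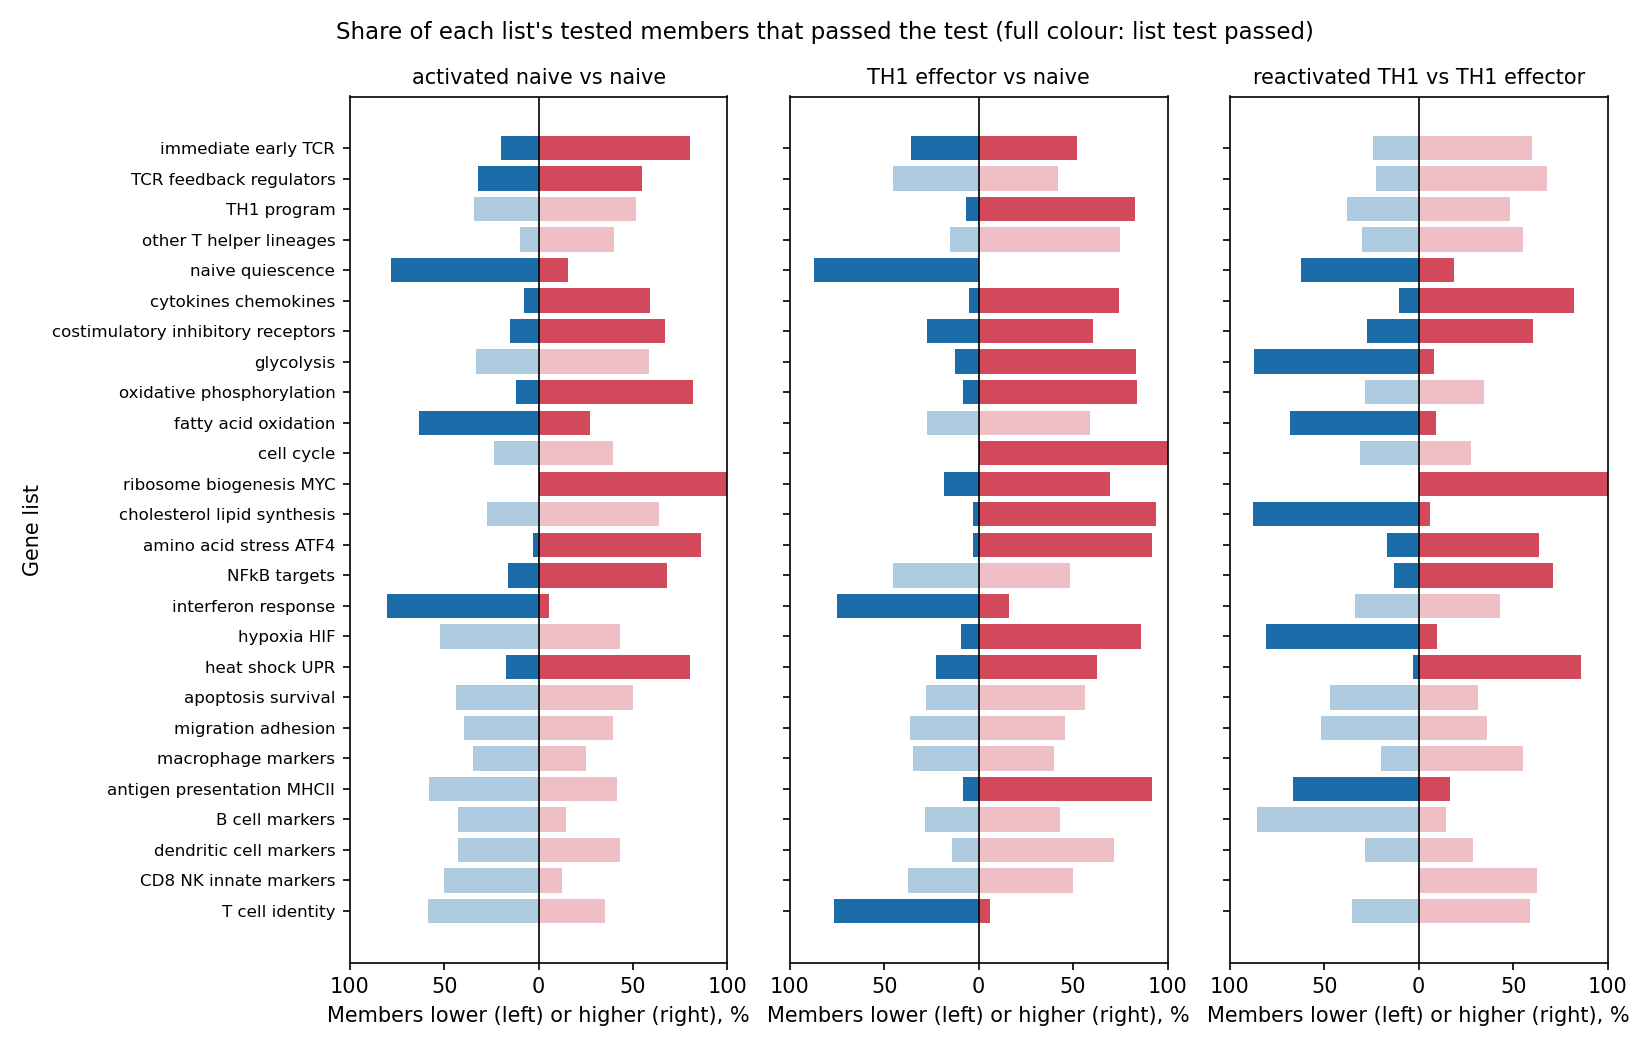
Percent of the tested members of 26 gene lists that were lower (blue, left) or higher (red, right) past the threshold in the comparisons of activated naive with naive, TH1 effector with naive and reactivated TH1 with TH1 effector cells. Full colour marks lists whose own test passed at the preset correlation, and the sex-linked list is left out. With an estimated correlation 1, 1 and 2 of these calls held in the 3 comparisons. All 51 cell cycle genes were higher in TH1 effector than in naive cells, and all 43 ribosome production genes were higher after stimulation of either cell type.

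The second comparison asked how TH1 effector cells differ from the naive cells they were made from. TH1 effector cells held transcripts of effector and activation genes that were near or at 0 in naive cells, and more transcripts of cell cycle, glycolysis and lipid synthesis genes. With an estimated correlation the adjusted p of these 3 lists was 0.0387, 0.137 and 0.322, so that the cell cycle call was kept and the others were lost. Gzmb, the gene of the cytotoxic protease granzyme B, went from 0.0260 to 864 CPM. Tnfrsf8 (CD30), the transcription factor gene Batf3 and Il21 had no counts in naive libraries and were at least 6870-, 6220- and 3250-fold higher than 3 counts over the group would give. Ifng was 1643-fold higher (log2 10.68, SE 1.24, adjusted p = 1.76e-15, and log2 11.28 without number 3), and Tbx21 was 822-fold higher (log2 9.68, SE 0.38, adjusted p = 1.17e-22). Ccr9, a chemokine receptor gene, fell from 87.8 to 0.0394 CPM, Slc16a5 fell from 151 to 0.120 CPM, and Tcf7, which encodes the naive and memory cell factor TCF-1, fell 8.82-fold (log2 −3.14, SE 0.15, adjusted p = 2.83e-09). A total of 10686 genes passed, 5613 higher and 5073 lower, with 3171 and 2060 of them at least 2-fold. The runs alone gave 10271 and 9549 genes, and a test against a minimum change of 1.5-fold gave 6695.

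All 51 cell cycle genes were higher in TH1 effector cells (adjusted p = 7.46e-47, and 0.0387 with an estimated correlation), including Ccna2 (0.0832 to 150 CPM) and Aurkb (1629-fold). This was the list whose call held with an estimated correlation. Of 24 glycolysis genes 20 were higher, among them Hk2 (0.140 to 310 CPM), the hexokinase that starts the pathway, and the lactate exporter gene Slc16a3 (0.348 to 261 CPM) (adjusted p = 7.16e-11, and 0.137 with an estimated correlation). The 3 that were lower included Pdk1 (3.90-fold), which restrains the oxidation of pyruvate in mitochondria. Of 29 TH1 programme genes 24 were higher and 2 lower (adjusted p = 4.19e-08, and 0.0996 with an estimated correlation). None of the 32 naive and quiescence genes was higher and 28 were lower, such as Il6ra (25.8-fold) (adjusted p = 7.78e-10, and 0.0996 with an estimated correlation). The amino acid and ATF4 list had 33 of 36 genes higher and Ddit4 lower (adjusted p = 1.25e-07, and 0.260 with an estimated correlation). Ddit4 did not pass in the first run alone (adjusted p = 0.390). Cholesterol and lipid synthesis had 31 of 33 genes higher, such as the desaturase gene Scd1 (0.0825 to 216 CPM), and Acss2 4.51-fold lower (adjusted p = 2.60e-05, and 0.322 with an estimated correlation). In the hypoxia list 18 of 21 genes were higher, among them Egln3 (3.67 to 539.9 CPM) and Nfil3 (1.09 to 114 CPM), and 2 were lower (adjusted p = 3.60e-05, and 0.301 with an estimated correlation).

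Of 39 cytokine genes 29 were higher and 2 lower, Cd40lg 2.88-fold (adjusted p = 0.000398, and 0.137 with an estimated correlation). Costimulatory and inhibitory receptor genes had 20 of 33 higher and 9 lower, such as Cd27 (6.10-fold) (adjusted p = 0.00238, and 0.137 with an estimated correlation). The oxidative phosphorylation list had 41 of 49 genes higher, with Cox5a at 3.58-fold, and 4 lower (adjusted p = 0.000377, and 0.522 with an estimated correlation). Ribosome production had 30 of 43 genes higher, such as Nhp2 (3.92-fold), and 8 lower, such as Utp20 (1.67-fold) (adjusted p = 0.00507, and 0.552 with an estimated correlation). Of 35 heat shock and protein folding genes 22 were higher, such as Sdf2l1 (7.95-fold), and 8 lower, such as Dnajb9 (3.62-fold) (adjusted p = 0.0315, and 0.552 with an estimated correlation), but not in the second run alone (0.106). The immediate-early list had 13 genes higher, with Tnfrsf9 at 421 CPM, and 9 lower, with Fos 37.9-fold lower (adjusted p = 0.000937, and 0.203 with an estimated correlation). Its call was lost with replicate number as a block (adjusted p = 0.195) and with no filter on low counts (0.187). Of 56 interferon-response genes 42 were lower, such as Oas2 (143 to 0.773 CPM), and 9 higher (adjusted p = 0.0115, and 0.739 with an estimated correlation). Mean log2 CPM of the list was 5.57 and 5.31 in TH1 effector numbers 5 and 6, against 4.64 to 5.14 in numbers 1 to 4, and without both numbers, left out after the data were seen, the adjusted p was 3.20e-05. As they were left out for their values on this list, the lower p adds no support to the call. MHC class II genes were higher in 11 of 12 cases, H2-Ab1 117-fold to 54.5 CPM, with H2-Ob 3.37-fold lower (adjusted p = 0.0190, and 0.301 with an estimated correlation). That call was lost when genes needed 10 CPM in a group (adjusted p = 0.142). The T cell identity list had 13 of 17 genes lower, such as Zbtb7b (2.87-fold), the factor that keeps cells CD4-positive, and Cd2 1.44-fold higher (adjusted p = 0.00278, and 0.260 with an estimated correlation). Adjusting over the list alone left the counts of passing members in these 16 lists the same. The remaining 11 lists, with adjusted p from 0.0622 to 0.986, were feedback regulators, other helper lineages, fatty acid oxidation, NF-kB targets, apoptosis and survival, migration and adhesion, the sex-linked genes and the markers of macrophages, B cells, dendritic cells and CD8, NK and innate cells. Other helper lineages (adjusted p = 0.0830) passed with the block (0.0350), with no filter on low counts (0.0242), at 10 CPM in a group (0.0477), in a fit of these groups only (0.0406), in the second run alone (0.0309), without number 1 (0.0416) and without numbers 5 and 6, left out after the data were seen (0.0270). Apoptosis and survival (0.0622) passed without number 1 (0.0272), 2 (0.0488) or 3 (0.0478), in the second run alone (0.00612) and in a fit of these groups only (0.0474). Of single markers of other cells, Cxcr2, known from neutrophils, had 1 count in the naive libraries and 14.8 CPM in TH1 effector libraries, a ratio of 2240 (95% counting interval 401 to 88400), Mmp9, also known from neutrophils, went from 0.0325 to 2.77 CPM, and the NK cell receptor gene Klrk1 had 1 count and 29.1 CPM, a ratio of 4200 (754 to 166000). The count of Cxcr2 was in naive number 3 and that of Klrk1 in naive number 5, and without that number, when no naive count is left, the fitted log2 fold change went from 10.36 to 11.68 and from 11.30 to 12.62, which are no bounds.

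The third comparison asked what TH1 cells change within 6 hours of meeting macrophages loaded with antigen. No group of TH1 cells met macrophages without antigen, so effects of the antigen and of the macrophages or their culture cannot be told apart. In reactivated TH1 cells most cytokine and chemokine genes rose, some of them by large factors, and most genes of glycolysis, of cholesterol and lipid synthesis and of the hypoxia list fell. With an estimated correlation the adjusted p of these 4 lists was 0.0172, 0.520, 0.345 and 0.372, so that the cytokine call was kept and the others were lost. Ifng rose 65.3-fold (log2 6.03, SE 0.29, adjusted p = 5.42e-14). Xcl1 went from 0.0221 to 2763 CPM, Ccl3 from 0.790 to 5540 CPM, Il3 from 0.175 to 953 CPM and Il2 from 0.0571 to 409 CPM. Ccl1 had no counts in TH1 effector libraries and was at least 18500-fold higher after reactivation. Cd70, which encodes the ligand of CD27, rose by 7.30 on the log2 scale. Myh11 (60.7 to 0.409 CPM), Rufy4 (27.3 to 0.281 CPM) and Cxcr2 (14.8 to 0.152 CPM) fell. Nr4a1 rose 2.77-fold (log2 1.47, SE 0.52, adjusted p = 0.00941). Without number 1 its log2 fold change was 0.88 (adjusted p = 0.0352), the call was lost without number 2 (1.31, adjusted p = 0.0505) and in the second run alone (0.46, adjusted p = 0.363), and over 17 alternatives the adjusted p ran from 0.00341 to 0.363. Tcf7 did not pass (log2 −0.61, SE 0.15, adjusted p = 0.0503), but it did in 9 of 17 alternatives. These were replicate number as a block (log2 −0.59, adjusted p = 0.0301), a fit of these groups only (0.000748), the DESeq2 Wald test (0.0268), DESeq2 size factors (0.0317), scaling by library size only (0.0255), at least 10 CPM in a group (0.0255), no run term (0.0458), and leaving out number 4 (0.0400) or 6 (0.0417). Over all 17 the adjusted p ran from 0.000748 to 0.216. The test called 10032 genes, 5025 higher and 5007 lower, of which 1670 and 2458 changed at least 2-fold. The runs alone gave 9453 and 8628, and a minimum change of 1.5-fold left 5408.

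In reactivated TH1 cells all 43 ribosome production genes rose (adjusted p = 3.11e-40, and 0.0145 with an estimated correlation), with Grwd1 at 6.60-fold and Utp20 at 6.51-fold. Of 39 cytokine genes 32 rose and 4 fell, among them Il24 (8.43-fold) and Ebi3 (3.20-fold) (adjusted p = 1.10e-09, and 0.0172 with an estimated correlation). These calls held with an estimated correlation, and the next 10 did not. Of the 12 lists called here 6 were higher and 6 lower, and with scaling by library size only 7 of 11 were higher, the feedback regulators being added, and 4 lower. Cholesterol and lipid synthesis fell in 29 of 33 genes, such as Acss2 (15.4-fold) and Mvd (10.2-fold), and rose in 2, one of them the fatty acid synthase gene Fasn (1.63-fold) (adjusted p = 5.39e-07, and 0.345 with an estimated correlation). Heat shock and protein folding genes rose in 30 of 35 cases, with Hsph1 at 4.39-fold and Hyou1 at 4.38-fold, and Edem1 fell 1.34-fold (adjusted p = 5.39e-07, and 0.271 with an estimated correlation). In the hypoxia list 17 of 21 genes fell, among them the mitophagy genes Bnip3 (20.2-fold) and Bnip3l (8.04-fold), and 2 rose, one of them the carbonic anhydrase gene Car12 (2.46-fold) (adjusted p = 0.000122, and 0.372 with an estimated correlation). NF-kB targets rose in 22 of 31 cases and fell in 4, such as Map3k8 (3.66-fold) (adjusted p = 0.000122, and 0.226 with an estimated correlation). Of 22 fatty acid oxidation genes 15 fell, with Acadl at 4.39-fold, and 2 rose (adjusted p = 0.000691, and 0.102 with an estimated correlation). Glycolysis fell in 21 of 24 genes, among them Aldoc (8.55-fold) and Slc16a3 (6.84-fold), and the lactate transporter gene Slc16a1 rose 2.57-fold (adjusted p = 0.000846, and 0.520 with an estimated correlation).

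Costimulatory and inhibitory receptor genes rose in 20 of 33 cases, with Cd160 going from 1.15 to 122 CPM, and fell in 9, with Ctla4 6.48-fold and Tnfrsf8 18.4-fold lower (adjusted p = 0.00604, and 0.227 with an estimated correlation). The amino acid and ATF4 list had 23 of 36 genes higher, such as Shmt1 (5.10-fold), and 6 lower, such as the lipoprotein receptor gene Vldlr (14.4-fold) (adjusted p = 0.00763, and 0.525 with an estimated correlation). Of 32 naive and quiescence genes 20 fell, such as the egress receptor gene S1pr1 (13.4-fold), and 6 rose, such as Slfn2 (13.6-fold) (adjusted p = 0.0297, and 0.520 with an estimated correlation). The call was lost without number 5 (0.0509) and with scaling by library size only (0.0533). MHC class II genes fell in 8 of 12 cases, such as H2-DMa (5.48-fold), and rose in 2 (adjusted p = 0.0297, and 0.372 with an estimated correlation). Their call was lost with replicate number as a block (0.0567), in the second run alone (0.0586), with scaling by library size only (0.0525) and when genes needed 10 CPM in a group (0.0998). Adjusted over the list alone, 1 more gene passed in the quiescence (27), cytokine (37), NF-kB (27), hypoxia (20) and heat shock (32) lists. The 15 lists not called, with adjusted p from 0.0568 to 0.965, were the immediate-early, feedback regulator, TH1 programme, other helper lineage, oxidative phosphorylation, cell cycle, interferon, apoptosis and survival, migration and adhesion, T cell identity and sex-linked lists and the markers of macrophages, B cells, dendritic cells and CD8, NK and innate cells. Feedback regulators (adjusted p = 0.0568), 21 of 31 genes higher, passed with the block (0.0292), with scaling by library size only (0.0291) or DESeq2 size factors (0.0443), with no filter on low counts (0.0378), in a fit of these groups only (0.0475), without number 1 (0.0253) or 3 (0.0311) and in the second run alone (0.0184). With no filter on low counts the macrophage list (adjusted p = 0.270) passed as higher (0.00425) and the B cell list (0.666) as lower (0.0464). Of 13 macrophage markers that averaged under 0.5 CPM in each other group, 10 were higher in every reactivated TH1 library than in any other library, among them Lyz2, lysozyme (5.98 CPM on average), and the Fc receptor gene Fcgr3 (1.85 CPM), both chosen after their values were seen. The cytotoxic gene Prf1, on the CD8, NK and innate list, rose from 4.88 to 35.9 CPM.

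The fourth comparison set the stimulated cells side by side, and as the labels used here do not name the stimulus of the naive cells, it is open whether both were stimulated in the same way. Reactivated TH1 cells held more cytokine, TH1 and cell cycle transcripts than activated naive cells, and less Nr4a1. Ifng was at 12950 against 0.482 CPM (log2 14.74, SE 0.38, adjusted p = 8.19e-18), Spp1, osteopontin, at 323 against 0.0388 CPM, and Il2 was 25.3-fold higher (log2 4.66, SE 0.27, adjusted p = 6.43e-12). Siglec5 and Cd70 had no counts in activated naive libraries and were at least 3200- and 1770-fold higher. Nr4a1 was 11.3-fold lower (log2 −3.49, SE 0.54, adjusted p = 2.88e-06), the chemokine receptor gene Ccr8 went from 72.9 to 0.977 CPM and Xkrx from 22.6 to 0.199 CPM. Tcf7 did not pass (log2 −0.38, SE 0.40, adjusted p = 0.213). There were 10045 genes past the threshold, 5464 higher and 4581 lower in reactivated TH1 cells, with 2900 and 1390 at least 2-fold. The runs alone gave 9417 and 8751, and a minimum change of 1.5-fold left 5412.

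Every one of 51 cell cycle genes was higher in reactivated TH1 cells (adjusted p = 3.00e-65, and 0.0064 with an estimated correlation), with Mki67 at 820.3 against 0.449 CPM (2046-fold, and log2 12.44 without number 6). Cytokine genes were higher in 36 of 39 cases and lower in none (adjusted p = 5.89e-12, and 0.0064 with an estimated correlation). The TH1 programme was higher in 26 of 29 genes and lower in 1 (adjusted p = 1.80e-11, and 0.0180 with an estimated correlation). Calls of the next 6 lists were lost with an estimated correlation. Ribosome production genes were lower in 32 of 43 cases, such as Polr1b (1.94-fold), and higher in 6, such as Npm1 (1.62-fold) (adjusted p = 0.00383, and 0.582 with an estimated correlation). The amino acid and ATF4 list was lower in 26 of 36 genes, such as the stress genes Ddit3 (4.88-fold) and Trib3 (3.25-fold), and higher in 5, Asns 13.5-fold, and its mean log2 fold change was 0.02, of opposite sign to the test (adjusted p = 0.00520, and 0.582 with an estimated correlation). Glycolysis was higher in 19 of 24 genes, with Tpi1 20.1-fold higher, and lower in 4, such as Eno2 (1.55-fold) (adjusted p = 0.0115, and 0.582 with an estimated correlation). The naive and quiescence list was lower in 20 of 32 genes, such as Klf2 (15.4-fold) and Il6st (8.38-fold), and higher in 5, with Il7r at 36.1-fold (adjusted p = 0.0160, and 0.582 with an estimated correlation). Without numbers 5 and 6, left out after the data were seen, it did not pass (0.0574). The hypoxia list was higher in 16 of 21 genes, such as P4ha2 (27.8-fold), and lower in 3, such as Kdm3a (1.39-fold) (adjusted p = 0.0418, and 0.657 with an estimated correlation). Its call was lost without number 1 (0.0504) and in the second run alone (0.0686). Macrophage markers were higher in 15 of 20 cases and lower in 3 (adjusted p = 0.0115, and 0.238 with an estimated correlation). Lgals3 was at 145 against 0.189 CPM and Nos2, inducible nitric oxide synthase, at 12.7 against 0.0249 CPM (log2 8.72, and 9.87 without number 1), and TH1 effector cells, before reactivation, already held 44.8 and 1.92 CPM. Adjusted over the list alone, 1 more gene of ribosome production passed (39) and the other counts were the same. The 18 lists not called had adjusted p from 0.0509 to 0.981. They were the immediate-early, feedback regulator, other helper lineage, costimulatory receptor, oxidative phosphorylation, fatty acid oxidation, cholesterol and lipid, NF-kB, interferon, heat shock, apoptosis and survival, migration and adhesion, MHC class II, T cell identity and sex-linked lists and the markers of B cells, dendritic cells and CD8, NK and innate cells. The costimulatory list, at 0.0509, passed without number 2 (0.0451), 3 (0.0404), 4 (0.0453) or 5 (0.0397), without both 5 and 6 (0.0270), in each run alone (0.0325 and 0.0330), with DESeq2 size factors (0.0452), at 10 CPM in a group (0.0405), with no run term (0.0443) and in a fit of these groups only (0.0445). CD8, NK and innate markers (0.0804) passed without number 5 (0.0243), without both 5 and 6 (0.0136), in the first run alone (0.0157) and with no run term (0.0443). With no filter on low counts the immediate-early and cholesterol lists passed as lower (0.0464 and 0.0155) and MHC class II as higher (0.0320), the last also in the second run alone (0.0336).

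The last comparison tested the difference itself, the response of TH1 cells to reactivation minus the response of naive cells to activation. Most genes of the immediate-early and amino acid lists had smaller or more negative responses in TH1 cells, and these calls held with an estimated correlation (adjusted p = 0.0204 and 0.0356). So did most genes of ribosome production, glycolysis, cholesterol synthesis and oxidative phosphorylation, while most naive and quiescence genes had less negative or larger ones, but these 5 calls were lost with an estimated correlation (adjusted p = 0.166, 0.151, 0.151, 0.533 and 0.151). The Nr4a1 response was 7.49-fold smaller in TH1 cells (log2 difference −2.91, SE 0.61, adjusted p = 0.000818). The log2 difference was −1.64 in the first run alone (adjusted p = 0.192), −4.06 in the second (0.000537) and −3.71 without number 1. The Tbx21 response was also smaller on the log2 scale (−7.35, SE 0.40, adjusted p = 1.19e-17). Those of Ifng (4.06, SE 1.30, adjusted p = 0.00272) and Cd44 (0.92, SE 0.10, adjusted p = 2.76e-09) were larger. Tbx21 had 17 counts in naive and 6004 in activated naive libraries, against 16520 in TH1 effector and 32719 in reactivated TH1 libraries. Of the 36 amino acid genes, 33 were already higher and 1 lower in TH1 effector than in naive cells. How far smaller log2 responses go with a higher start was looked at for Nr4a1 only. Il7r (5.97) fell less in TH1 cells, and Tcf7 (2.76), which did not pass on reactivation, had a less negative response. The difference passed for 8553 genes, 4313 positive and 4240 negative, of which 1882 and 1937 were at least 2-fold. The runs alone gave 7389 and 6642, and a minimum difference of 1.5-fold left 4436. Across genes, which are not independent replicates, the responses correlated at r = 0.524 (0.496 and 0.501 in the runs alone), and they shared no library. Of the genes called, 3572 rose in both responses against 2077 for independent lists, and 3375 fell in both against 2030. Another 766 rose in naive and fell in TH1 cells against 2069 for independent lists, and 695 fell in naive and rose in TH1 cells against 2037.

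The amino acid and ATF4 list had a smaller or more negative response in TH1 cells for 32 of 36 genes and a larger one for none (adjusted p = 6.82e-24, and 0.0356 with an estimated correlation), with Slc7a11 at −6.81 (−7.43 without number 2). The immediate-early list was lower for 17 of 25 genes and higher for 6, among them Jun (3.44), which fell in both cell types and fell further in naive cells (adjusted p = 1.57e-10, and 0.0204 with an estimated correlation). These calls held with an estimated correlation and those of the next 12 lists did not. Ribosome production was lower for 37 of 43 genes, with Odc1 at −3.68, and higher for 1 (adjusted p = 8.32e-12, and 0.166 with an estimated correlation). Cholesterol and lipid synthesis was lower for 28 of 33, with Lss at −3.44, and higher for 2, with Acss2 at 1.03 (adjusted p = 3.39e-12, and 0.151 with an estimated correlation). Glycolysis was lower for 16 of 24, with Hk2 at −9.15, and higher for 4, with Pdk1 at 1.60 (adjusted p = 2.28e-10, and 0.151 with an estimated correlation). The naive and quiescence list was higher for 23 of 32 and lower for 2, among them the chromatin organizer gene Satb1 (−2.22) (adjusted p = 1.47e-06, and 0.151 with an estimated correlation). Oxidative phosphorylation was lower for 37 of 49, with Cox5a at −1.30, and higher for 2 (adjusted p = 0.000286, and 0.533 with an estimated correlation). Costimulatory and inhibitory receptor genes were lower for 20 of 33, with Slamf7 at −7.32, and higher for 7, with Cd160 at 5.60 (adjusted p = 0.00719, and 0.151 with an estimated correlation). The hypoxia list was lower for 13 of 21, with Vegfa at −6.36 and Bnip3 at −3.67, and higher for 2 (adjusted p = 0.00161, and 0.461 with an estimated correlation). Heat shock and protein folding was lower for 25 of 35, with Hspa4l at −3.26, and higher for 7, with Dnajb1 at 1.22 (adjusted p = 0.00350, and 0.461 with an estimated correlation).

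The interferon-response list was higher for 40 of 56 genes, with Mx2 at 5.58 and Ifit3 at 5.55, and lower for 5, with Irf8 at −4.38 (adjusted p = 0.00113, and 0.740 with an estimated correlation). Without numbers 5 and 6, whose activated naive libraries held the list higher, the adjusted p was 6.50e-11. These numbers were left out for their values on this list, so the lower p adds no support to the call. Other helper lineages were lower for 8 of 20, with the chemokine receptor genes Ccr8 at −9.30 and Ccr4 at −7.69, and higher for 2 (adjusted p = 0.0227, 0.170 with an estimated correlation, 0.0834 with replicate number as a block and 0.0724 with no filter on low counts). Macrophage markers were higher for 8 of 20 and lower for 2 (adjusted p = 0.0227, 0.187 with an estimated correlation, 0.0646 with the block and 0.0649 in the second run alone). Of its members the protease genes Ctsd (1.86) and Ctsb (1.36) were at 314 and 151 CPM in naive libraries, which had met no macrophages as far as the labels tell. T cell identity genes were higher for 8 of 17, with Thy1 at 3.12 and the receptor chain gene Cd247 at 3.28, and lower for 7, with Cd5 at −1.44 and Zap70 at −1.55. That list passed (adjusted p = 0.0227, and 0.461 with an estimated correlation) with a median of −0.04 and a mean of 0.59, and the call was lost with the block (0.347) and with no filter on low counts (0.298). Adjusted over the list alone, 24 immediate-early genes and 9 macrophage markers passed and the other counts were the same. The 13 lists not called, with adjusted p from 0.105 to 0.969, were feedback regulators, the TH1 programme, cytokines, fatty acid oxidation, cell cycle, NF-kB targets, apoptosis and survival, migration and adhesion, MHC class II, the sex-linked genes and the markers of B cells, dendritic cells and CD8, NK and innate cells. In the second run alone feedback regulators (0.211) and apoptosis and survival (0.212) passed as lower (0.0301 and 0.0309). CD8, NK and innate markers (0.105) passed as higher in the first run alone (0.0452) and without numbers 5 and 6 (0.0334).

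**Figure D3:**
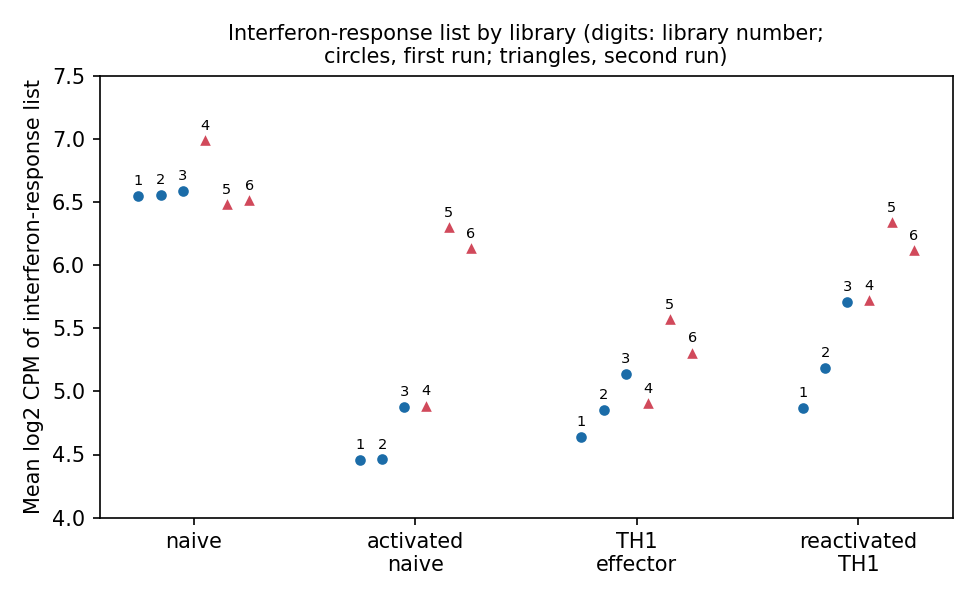
Mean log2 CPM of the 56 tested interferon-response genes in each library, by group, with the library number at each point. Naive libraries lay between 6.48 and 6.99, and in activated naive cells numbers 5 and 6 (6.30 and 6.13) lay above the other 4 libraries.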

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

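The splits of the libraries were planned, and the tests of the Nr4a1, macrophage and interferon patterns were chosen after the result was seen. The responses of the naive and TH1 cells differed by a test of the difference itself for 8553 genes and 14 lists. With an estimated correlation the calls of 2 of these lists held and those of 12 were lost. Among the genes named, the log2 difference was negative, TH1 minus naive, for Nr4a1 (−2.91), Tbx21 (−7.35), Odc1 (−3.68), Slc7a11 (−6.81), Slamf7 (−7.32), Hspa4l (−3.26), Irf8 (−4.38), Hk2 (−9.15), Cox5a (−1.30), Bnip3 (−3.67), Ccr8 (−9.30), Lss (−3.44), Satb1 (−2.22), Vegfa (−6.36), Ccr4 (−7.69), Cd5 (−1.44) and Zap70 (−1.55). It was positive for Ifng (4.06), Tcf7 (2.76), Il7r (5.97), Jun (3.44), Dnajb1 (1.22), Ifit3 (5.55), Pdk1 (1.60), Acss2 (1.03), Cd160 (5.60), Cd44 (0.92), Mx2 (5.58), Ctsd (1.86), Ctsb (1.36), Thy1 (3.12) and Cd247 (3.28). Outside the gene counts, reads aligned to more than 1 place were 7.53% in TH1 effector libraries, against 5.92% in naive libraries.

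The smaller Nr4a1 response of reactivated TH1 cells is the reading of the reporter's own gene. A higher resting level in TH1 effector cells was argued against by a log2 difference of −0.59 from naive libraries (SE 0.28, adjusted p = 0.251), where a higher level was needed, and a run difference as the whole source by the value in the second run alone, −4.06 (adjusted p = 0.000537), although the first run alone gave −1.64 (0.192) and all settings −4.06 to −1.64, with adjusted p from 9.14e-06 to 0.192. Fewer cells responding as naive cells do, with the others staying as at rest, were argued against as the whole source, since the Nr4a1 responses would then put the share of responding cells at 8.96%, or 37.9% with both moved by 2 SE, and no gene could fall by more than 1.61-fold, whereas 2527 genes fell further by over 2 SE. This reaches only the case in which the other cells stayed as at rest. If they also changed in the culture with macrophages, the falls say nothing on the share of responding cells, and a small share stays open. A response weaker across most genes cannot be told apart from a change of this gene, since 99 of 1072 genes up at least 2-fold in both responses (9.24%) had a larger response in TH1 cells and 578 a smaller one. A stimulus that differed between the cell types (that of the naive cells is not named in the labels used here) and the cell type itself stay open as untested biological explanations.

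Macrophage transcripts were present in reactivated TH1 libraries, with Lyz2 at 5.98 CPM and Fcgr3 at 1.85 CPM. RNA of the macrophages of the co-culture may account for them, since Xist in the 3 reactivated libraries of numbers with Y-linked genes (0.593 to 0.870 CPM, 13 to 24 counts) lay above the 9 libraries of the other groups (0 to 0.196 CPM, 0 to 4 counts), with a 1-sided exact permutation p of 0.0156 within numbers, the smallest that 64 permutations can give. Reads assigned to the wrong library were argued against by the lowest reactivated value being 3.03 times the highest of the others. The macrophage explanation stays open and cannot be told apart from expression by the T cells, because 3 of 13 low markers (Cd14, Tyrobp and Chi3l3) were not separated, the animals of the macrophages are not given, and the cells had been sorted. Of 31 markers in the files 15 reached 0.5 CPM in a group other than reactivated TH1, and 2 are also on another list.

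Interferon-response genes were higher in numbers 5 and 6 than in the other numbers in activated naive, TH1 effector and reactivated TH1 libraries. A run difference as the whole source was argued against by number 4, of the same run, which lay at least 0.396 below both in mean log2 CPM in these 3 groups. A difference already present in the naive cells was argued against by the rank sum of 11 of numbers 5 and 6 there, the lowest 2 of 6 libraries. These places are part of the pattern as it was picked after the data were seen, so they are not separate support. Without numbers 5 and 6 the list's adjusted p (camera, preset correlation) was 6.46e-06 in activated naive and 3.20e-05 in TH1 effector against naive cells. For the difference between the responses it was 6.50e-11. The numbers were left out for their values on this list, so these p-values add no support to its calls. With all libraries and an estimated correlation the list was not called in these 3 comparisons (adjusted p = 0.843, 0.739 and 0.74). The design gives no group that sets these numbers apart, so no biological explanation was tested.

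Single libraries that stood apart from the other 5 of their group were looked for in 458 groups of named genes with at least 1 CPM and in 32 groups of library measures. They were found in 31 and 0, and chance gives about 1 in 20. In naive libraries these were number 1 for Odc1 (45.9 CPM, the others 34.8 to 38.8), Jun (841, 429.7 to 528), Nsg2 (419, 356 to 379) and Klf2 (597, 294 to 395), number 2 for Bcl2l1 (33.4, 14.3 to 20.3), number 3 for Cd27 (396, 430.1 to 445), number 4 for Irf8 (18.1, 4.66 to 9.18), and number 5 for Mx2 (12.2, 15.9 to 18.1). In activated naive libraries they were number 1 for Spry1 (424, 554 to 596), number 4 for Ccl3 (7.52, 2.73 to 4.21), number 5 for Ctsd (50.5, 55.4 to 57.2), and number 6 for Nsg2 (4.46, 2.31 to 2.75), Gzmb (5.24, 0.705 to 1.59) and Bnip3l (26.3, 22.4 to 23.6). In TH1 effector libraries they were number 1 for Rgs16 (7.11, 3.71 to 4.91), Aurkb (125, 79.4 to 94.7) and Shmt1 (50.5, 38.4 to 40.2), number 4 for Utp20 (68.6, 56.6 to 60.1), Cd44 (180.0, 121 to 142) and Ccr4 (161.97, 108 to 124), number 5 for Tcf7 (415, 205 to 277), Ddx60 (10.4, 3.66 to 5.83) and Cd160 (2.01, 0.798 to 1.10), and number 6 for Fosb (31.5, 9.70 to 17.5). In reactivated TH1 libraries they were number 1 for Fosb (11.2, 3.18 to 6.04), number 3 for H2-Ob (0.639, 1.32 to 1.49), number 4 for Fasn (636, 808 to 883), and number 5 for Tnfrsf8 (4.43, 7.19 to 8.75), Nfil3 (17.9, 31.9 to 35.9), Cd27 (327, 259 to 280.1) and Ctsb (223, 240.8 to 249).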

How the results depend on the processing

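All settings and splits were planned except leaving out numbers 5 and 6, which was chosen after the result was seen. Of 364 results of single genes 328 kept their direction and their side of the threshold in every setting that gave them a value, which was all 17 settings for 275 of them and at least 15 for the rest. Of 6095 values in all, 5985 did so, 89 lost the call, 20 gained it and 1 turned: Cxcr3 in reactivated TH1 against activated naive cells was −0.40 (adjusted p = 0.00772) and 0.0615 in the first run alone (0.679), and the cause was not tested. With an estimated correlation 1, 1, 2, 3 and 2 lists were called in the order of the comparisons in the report, and with fry, which tests whether a list's genes move one way and does not compare them with other genes, 22, 26, 23, 22 and 21. The test against a 1.5-fold minimum change, which is stricter by construction, called 6914, 6695, 5408, 5412 and 4436 genes. The correlation of the responses was 0.422 with no filter on low counts and 0.593 with at least 10 CPM in a group. The cause was not tested. With each number left out in turn, the genes called ran from 9976 to 10164, 10374 to 10572, 9603 to 9874, 9623 to 9887 and 7947 to 8244, the lists from 10 to 12, 16 to 18, 11 to 13, 8 to 11 and 14 to 14, and the correlation from 0.511 to 0.526. Without numbers 5 and 6 the genes were 10072, 10560, 9821, 9835 and 8082 and the lists 11, 17, 12, 10 and 15. The DESeq2 Wald test called 10345, 10714, 10083, 10124 and 8802 genes. Scaling by library size alone moved the median log2 fold change of all genes to −0.14 in activated naive against naive and −0.12 in reactivated TH1 against TH1 effector cells, from 0.00 in both, and changes are given relative to the median gene. Depth limits genes with few counts, such as Ifng at 0.112 CPM in naive and 0.482 CPM in activated naive libraries, whose call ended without number 4 or 6.

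With replicate number as a block, which the pairing of the libraries allows, 10336, 10746, 10111, 10118 and 8620 genes and 11, 16, 12, 9 and 11 lists were called, and the correlation was 0.523. The block changed the calls of the feedback regulators (0.153 in activated naive and 0.0292 in reactivated TH1 cells), the immediate-early list (0.195) and other helper lineages (0.0350) in TH1 effector cells, MHC class II (0.0567) in reactivated TH1 cells, and other helper lineages (0.0834), macrophage markers (0.0646) and T cell identity (0.347) in the difference between the responses. Of the genes named it changed that of Tcf7 in reactivated TH1 cells (0.0301), and it changed no other call of a named gene or list.

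Other splits of the same libraries were fitted without the run term. In every comparison the real split called the most genes, of 100, 100, 100, 100 and 70 splits. It called 9596, 10124, 9545, 9264 and 8235 genes, against 2, 0, 2023, 0 and 0 in the highest other split. A split that mixes the groups moves their difference into the spread within groups, so low counts there follow from the size of that difference. The rank of the real split therefore shows only that the gene counts go with the groups. The split with 2023 genes exchanged 1 library between the groups, and splits by run called 2, 2, 2 and 3 genes in the 4 comparisons of groups. As many lists as in the real splits (14, 16, 12, 12 and 14) were called in 1, 4, 30, 12 and 7 of them, with highest others of 13, 16, 21, 13 and 15. Under the limit set beforehand, counts as high were rare for the first 2 comparisons and not for the last 3. Splits that exchange few libraries keep much of the real difference, and the list test ranks a list against other genes. Such splits can call lists through that difference, so the list counts cannot decide on chance either way. Among the 32 splits that part all 6 pairs as the real one does, 1, 1, 14 and 6 called as many lists, the others calling up to 11, 15, 17 and 13, and 1 in each comparison called as many genes, the others none. For the correlation, computed here from mean log2 CPM differences, the real split was the largest of 100 in size (0.537 against up to 0.53). The other splits regroup the same libraries and keep part of the real differences, so this rank cannot decide on chance.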

Other observations

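The hypothesis and its test in the last paragraph were written before the result was seen, and the genes of the first 2 paragraphs were chosen after their values were seen. The list of migration and adhesion genes did not pass as a group in any comparison, and its members changed in both directions. In stimulated naive cells 13 of 33 rose and 13 fell (list adjusted p = 0.301, and 26 passed when adjusted over the list alone), and in reactivated TH1 cells 12 rose and 17 fell (0.12), or 30 together when adjusted over the list alone. Of all 12584 genes 5201 rose and 5102 fell in stimulated naive cells, and 5025 rose and 5007 fell in reactivated TH1 cells. Changes in both directions therefore do not set this list apart. The integrin genes Itgb7 and Itga4 fell in both cell types, and Itgb1 rose in both. Itgb7 went from 874 to 7.22 CPM in naive cells (edgeR adjusted p = 5.51e-24) and from 421 to 76.2 CPM in TH1 cells, and Itga4 from 756 to 15.2 and from 151 to 46.5 CPM. Itgb1, another partner of the product of Itga4, rose from 62.4 to 152 and from 165.2 to 368 CPM.

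Genes of apoptosis and survival did not pass as a list either, with 16 of 32 higher and 14 lower in stimulated naive cells (adjusted p = 0.914), 18 higher and 9 lower in TH1 effector cells (0.0622), and 10 higher and 15 lower on reactivation (0.407), and adjusted over the list alone 30, 27 and 25 passed. Of all genes tested 81.9%, 84.9% and 79.7% passed in these comparisons, so passing by most members does not set the list apart. Bcl2, which protects cells from death, was at 129 CPM in naive, 167.95 in activated naive and 979.6 CPM in TH1 effector libraries and fell to 142 CPM on reactivation. Its small rise in activated naive cells (log2 0.37) did not pass in the first run alone (log2 0.17, adjusted p = 0.135) or with scaling by library size only (log2 0.20, adjusted p = 0.0703). Bcl2l1, a relative with the same role, rose from 19.3 to 72.3 CPM and from 105 to 291 CPM. Pmaip1, which promotes death, went from 1.82 CPM in naive to 98.1 CPM in TH1 effector libraries (log2 5.76) and fell to 52.5 CPM on reactivation.

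A hypothesis was that stimulation brings naive and TH1 cells closer together. It was tested as the slope of the TH1 minus naive difference after stimulation on that at rest, across genes with at least 10 CPM in a group (9609), taking each side from a different run. The slopes were 0.561 and 0.610, against 0.970 and 0.998 for the resting difference of one run on that of the other, as the hypothesis predicted. A slope also falls when stimulation changes which genes differ, so it cannot show alone that differences shrink. The SD of the log2 differences was 2.15 at rest and 1.73 after stimulation, a smaller spread over these genes. Quiescence genes were closer after stimulation in 23 of 31 cases, cell cycle genes in 28 of 51, TH1 genes in 15 of 28 and cytokine genes in 18 of 34. The share over all genes was not computed, so these counts do not set the lists apart. Genes are not independent replicates, and the stimulus of the naive cells is not named in the labels used here, so the share of the stimulus in the smaller spread could not be separated.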
